A study of Rattus norvegicus with 16 samples.

How the data were processed

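Per its labels, the series profiled RNA from rat levator ani satellite cells, the muscle stem cells of a pelvic muscle whose size depends on androgens. Cells at passage 5 received vehicle (0.2% DMSO) or 10 nM of a nonsteroidal androgen receptor agonist (NARA) for 4 h or 48 h, in medium whose serum had been stripped with charcoal, which removes steroids. The 4 groups held 4 arrays each, 16 in all. The titles call the samples biological replicates without naming separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

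Per the labels' protocols, 5 µg of total RNA was labelled with biotin for Affymetrix Rat Genome 230 2.0 arrays, with 1 array per sample. The extraction is given as a Trizol procedure in the labels' protocols and as a column kit in the series' design text, and which applied to which sample was not given in the sources used here. Each deposited intensity is a MAS5 signal on a linear scale, per the submitters' processing notes, and per the series' design text the authors scaled every array to a trimmed mean of 1500. The deposited values bore this out, with a trimmed mean between 1500.45 and 1500.56 on every array. Detection calls were not used here. Per the series' design text, the authors left out 3 arrays for low correlation and a distant position in a principal component plot. These were NARA 4 h replicates 1 and 4 and vehicle 48 h replicate 1, and the same 3 arrays were left out of the comparisons here. The remaining 13 arrays were 4 vehicle 4 h, 2 NARA 4 h, 3 vehicle 48 h and 4 NARA 48 h, and their number limits the precision of every comparison.

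The table held 31099 probe sets, of which 57 were Affymetrix controls and were set aside. Of the other 31042, the platform annotation used here gave 20826 exactly 1 gene symbol, 436 several and 9780 none. Gene identifiers of 20758 of the probe sets with 1 symbol were found in the RefSeq gene table of the rat, and 0 symbols needed an update. Signals were transformed as log2(signal + 50), so a fold change understates the change of dim probe sets. Probe sets with a mean signal of at least 300 over the 13 arrays were tested. These were 20904, of which 15458 had 1 symbol, 343 several and 5103 none, and they covered 11286 genes. Where a gene had several probe sets, the brightest stood for it.

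A model of group means was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 9 residual degrees of freedom and 2.4 prior degrees of freedom. All 4 groups shared 1 estimate of the spread. The 5 contrasts were NARA against vehicle at 4 h, the same at 48 h, the difference between those effects, 48 h against 4 h in vehicle, and 48 h against 4 h in NARA. Two-sided p-values from limma were adjusted by the Benjamini-Hochberg method over all probe sets tested, with a threshold of 0.05. Errors of log2 changes are standard errors from limma, and signals are given as mean ± SD over arrays.

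A total of 35 gene lists were fixed beforehand with 759 members, of which 679 were found on the array. Each list was set against all other genes with camera, at a preset correlation between genes of 0.01 and with at least 4 measured members, and adjusted over the lists of a comparison. Camera with a correlation estimated from the data and the rotation test fry were run as alternatives. No camera call in any of the 5 comparisons held with an estimated correlation. Members past the threshold were counted over all probe sets tested and again adjusted over the list alone.

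The design, the gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took, per comparison, up to 10 higher and 10 lower genes with the greatest fold change among those that passed and whose arrays did not overlap between groups. The overlap condition was dropped for the difference of effects. Where fewer than 5 genes passed, the 5 higher and 5 lower genes with the smallest p were taken. It added up to 4 members of each list by p, and a fixed set of genes that were always named, among them Fkbp5, Igf1, Mstn, Fst, Pax7, Myf5, Myod1, Myog, Des and Mki67. Another member of that set is not reported here. Pax7 and Myf5 had no probe set in the annotation used here, and Mstn and Myod1 lay below the minimum signal.

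The statistics were tested on simulated data drawn from the real means and spreads, with 200 changed probe sets of 20904 in each of 5 runs. For the 4 h comparison, 13.1% of 1.5-fold, 48.3% of 2-fold and 84.2% of 4-fold changes were recovered, and 5.14% of calls were false. For NARA against vehicle at 48 h these were 21.8%, 54.5% and 86.5%, with 4.38% false calls. Camera recovered 4 of 5 simulated lists shifted by 0.3 log2 at 4 h and 5 of 5 at 48 h. It called 0 of the lists that shared no gene with the shifted list, and calls of overlapping lists were not counted. The simulated noise was independent between probe sets, so it cannot show how often camera makes false calls among correlated genes.

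Alternatives were all 16 arrays with and without array weights, only the groups compared, offsets of 1 and 200, no signal minimum or a minimum of 1000, quantile and median scaling, a trended and robust prior, other probe sets of a gene, the replicate number as a block, and leaving out each array in turn. A fit of 14 arrays, with vehicle 48 h replicate 1 put back, was added after the data had been seen. No scaling alternative moved the share of higher calls by over 10 percentage points. Array quality was described by correlations, principal components, the 3'/5' signal ratios of the actin and Gapdh controls, and 18 marker lists of other tissues and cells, written before they were computed.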

Results

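By their labels, the 16 arrays measured gene expression in rat levator ani satellite cells, 4 per group, after vehicle or 10 nM NARA for 4 h or 48 h. The 13 arrays kept by the authors correlated with each other at r between 0.930 and 0.956 across probe sets, which are not independent replicates. The median signal of the 16 arrays lay between 539 and 786. NARA 4 h replicates 1 and 4 correlated with the other 14 arrays at 0.645 to 0.673, and with each other at 0.894. In both arrays a list of 12 liver genes had a median log2 difference of 8.73 and 8.84 from the vehicle 4 h mean. A list of fibroblast markers lay at -2.63 and -2.66. Vehicle 48 h replicate 1 correlated with the 13 arrays at 0.922 to 0.933.

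**Figure D1:**
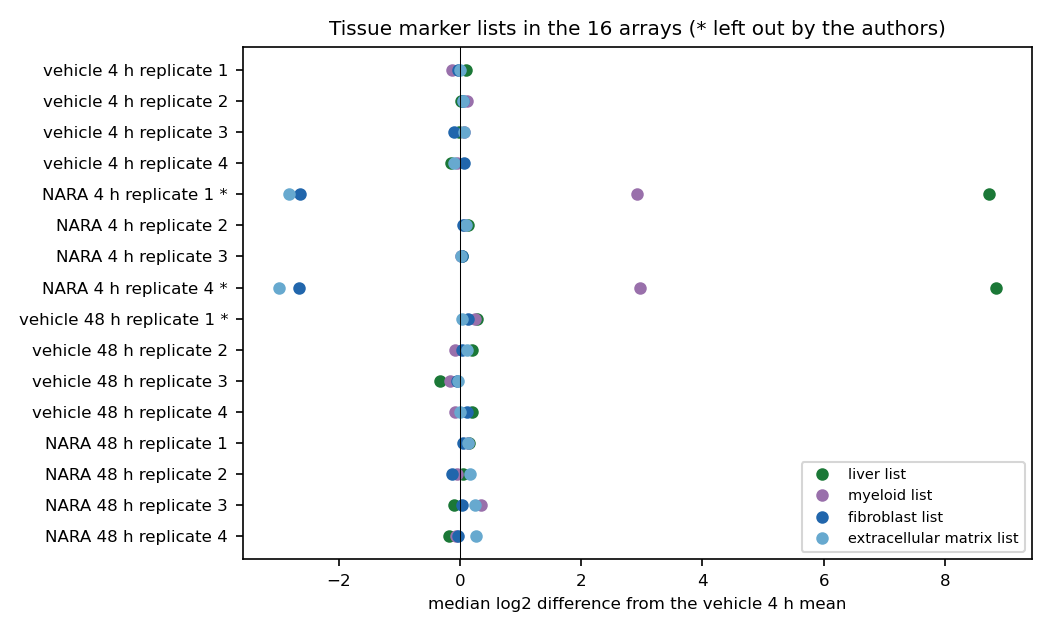
Median log2 difference of 4 marker lists from the vehicle 4 h mean (horizontal axis) in each of the 16 arrays (vertical axis), with 1 point per list and array and a star for arrays left out by the authors. The liver list lay at 8.73 and 8.84 in NARA 4 h replicates 1 and 4, while the fibroblast list lay at -2.63 and -2.66.

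The first comparison asked which genes differed between NARA and vehicle after 48 h. Igf1, a growth factor that drives muscle growth, rose 3.04-fold, from a signal of 29840 ± 4088 (SD, n = 3) in vehicle to 90360 ± 7967 (SD, n = 4) in NARA. Fst, a secreted antagonist of myostatin and activin, rose 4.46-fold from 616 ± 218 to 2830 ± 185. Fkbp5, a chaperone of steroid receptors and a classical androgen target, rose 3.49-fold from 758 ± 71.7 to 2776 ± 292. Cxcr4, a chemokine receptor of satellite cells, was 8.13-fold lower, at 590.0 ± 218 against 4923 ± 401. Ptgs2, the inducible enzyme of prostaglandin synthesis, was 4.97-fold lower, at 893 ± 170 against 4585 ± 372.

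With limma, 586 of 20904 probe sets passed the threshold, 285 higher and 301 lower in NARA. Their brightest probe sets stood for 362 genes, 193 higher and 169 lower. The median size of the log2 change was 0.76, and 169 probe sets changed at least 2-fold. The arrays of the groups did not overlap for any of the 586, while 14.7% of all probe sets showed no overlap against 5.71% by chance. Without vehicle 48 h replicate 3 the count was 310, and without vehicle 48 h replicate 2 it was 321. It was 218 with only the 48 h groups in the fit, 36 with all 16 arrays, 355 with no signal minimum, 1069 with a minimum of 1000 and 1098 with a trended and robust prior. With the replicate number as a block it was 312. Of the 60 named genes that passed at 48 h, 37 also passed without each array in turn, and all 60 kept their direction.

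Among the 10 genes with the greatest rise at 48 h, Bmper, a secreted regulator of bone morphogenetic proteins (BMPs), rose by 3.34 log2 units (SE 0.397, adjusted p = 0.000832). Ces1d, a carboxylesterase, rose by 3.16 (SE 0.280, adjusted p = 0.000137). Sult1a1, a sulfotransferase of phenols, rose by 2.70 (SE 0.161, adjusted p = 2.75e-05). The transcription factor Tfcp2l1 rose 9.42-fold, the secreted protein Crispld2 7.76-fold and Enpp1, an enzyme that makes pyrophosphate, 6.52-fold. Mfap2, a protein of elastic microfibrils, rose by 2.60 log2 units, the formin Fhod3 by 2.50, Ctnnal1 by 2.35 and Tpd52l1 by 2.31. Among the lower genes, Egr2, an immediate early transcription factor, changed by -1.80 (SE 0.151, adjusted p = 0.000110). Tmem26 changed by -2.33, the kinase Nrk by -1.90, the sodium channel Scn7a by -1.82 and the gap junction protein Gjb2 by -1.74. The transcription factor Osr2 changed by -1.56, Wfdc18 by -1.53 and Mettl7a by -1.49.

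**Figure D2:**
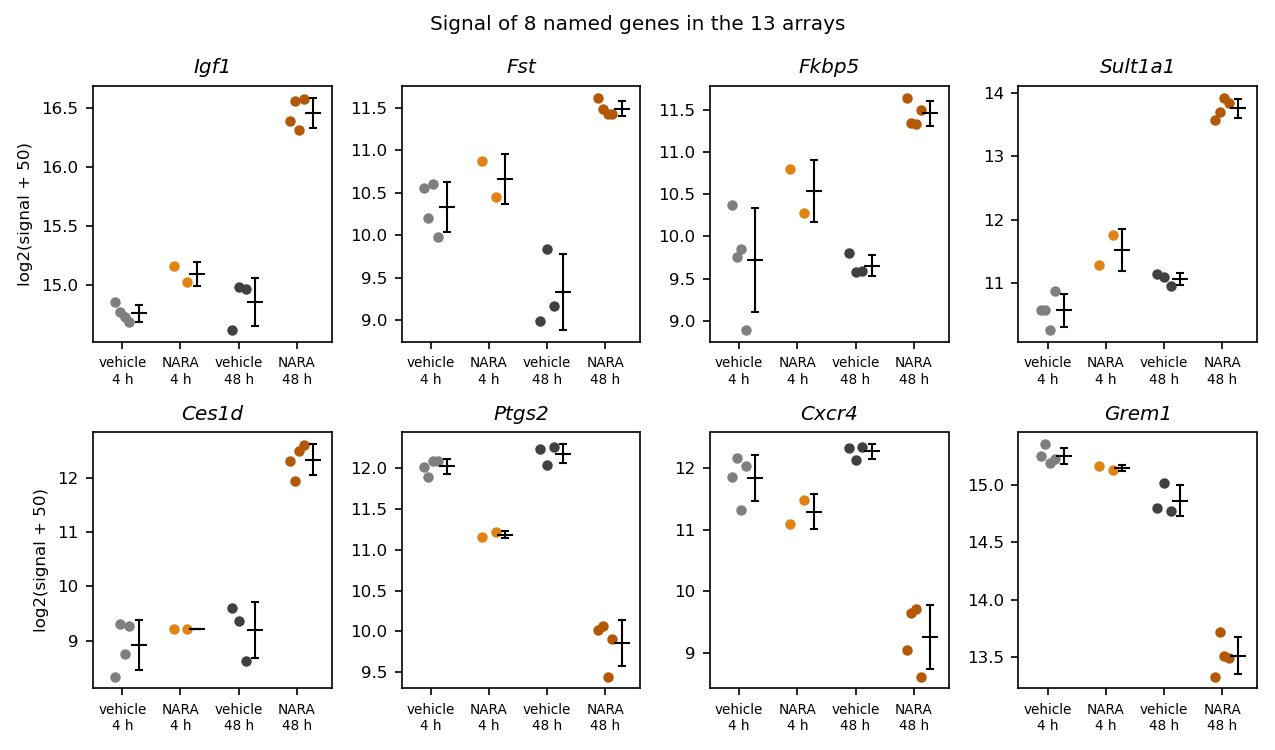
Signal of 8 named genes as log2(signal + 50) (vertical axes) in the 13 arrays by group (horizontal axes), with a point per array and, beside the points, the group mean with its SD. Igf1 rose by 1.60 log2 units and Cxcr4 fell by 3.02 log2 units with NARA at 48 h.

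Genes of androgen and steroid response moved in both directions at 48 h. Of 19 measured members of the androgen-responsive list, 3 rose (Igf1, Fkbp5 and Tsc22d3) and 1 fell (Cited2, at -0.64 log2). Adjusted over the list alone, 3 were higher and 2 lower. Camera gave adjusted p = 0.584, and fry, which does not compare the list with other genes, placed it higher with adjusted p = 0.0458. Of 13 glucocorticoid-responsive genes, 5 rose and 0 fell, the same counts as adjusted over the list alone. These included Tsc22d3, a leucine zipper protein induced by steroids, by 1.02 (SE 0.121), and the kinase Sgk1 by 0.81 (SE 0.0942). Both lists hold Fkbp5 and Tsc22d3. Camera placed the glucocorticoid list higher with adjusted p = 0.00315, and adjusted p = 0.0850 with an estimated correlation. Of 13 steroid receptors and coregulators, 2 fell: Nr3c1, the glucocorticoid receptor, at -0.54 log2 and Tgfb1i1, a coactivator of steroid receptors, at -0.53. Polyamine metabolism, which includes known androgen targets, had 1 lower member of 13, the spermine synthase gene Sms, at -0.97 (SE 0.104).

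Growth factor, BMP and TGF-beta genes changed with NARA at 48 h as single members, and none of these lists passed camera. Among 20 genes of IGF and growth factor signalling, Igf1 and Fgf7 rose, the latter by 0.97 log2, and the PDGF receptor gene Pdgfra fell by 0.75. With p adjusted over the list alone, 3 were higher and 3 lower. Of 18 genes of myostatin, activin and BMP signalling, Fst and Id2 rose, the latter by 1.08, and the BMP antagonist Grem1 was 2.55-fold lower, at 11700 ± 1332 against 29830 ± 2833. Of 17 TGF-beta targets, Tgfb2 rose 2.52-fold, Ccn2 by 1.01 log2 and Lox, which crosslinks collagen, by 0.43. Of these, 3 were higher and 4 lower when adjusted over the list alone. Of 23 Wnt and Notch genes, 1 rose (Hes1, by 0.48) and 4 fell, among them Sfrp2 at -0.57, Dkk3 at -0.59 and Ccn4 at -0.64. Another probe set of Dkk3 lay at 0.59 and did not pass.

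The extracellular matrix list also split at 48 h. Of 30 measured members, 4 rose and 3 fell, and adjusted over the list alone 8 were higher and 7 lower. Col6a1 rose 1.89-fold, Col11a1 by 1.035 log2 and Thbs2 by 0.70, while the collagen-binding proteoglycan Lum was 2.08-fold lower, at 21040 ± 1399 against 43770 ± 2634. Of 16 fibroblast markers, 2 fell, Lum and Pdgfra. Among 19 matrix proteases and inhibitors, the plasminogen activator gene Plau rose by 0.89.

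Of 27 measured genes of the unfolded protein and amino acid responses, 22 had a positive log2 change at 48 h and 5 rose, with 10 higher and 0 lower adjusted over the list alone. Manf rose 1.78-fold, Hspa5, the main chaperone of this compartment, 1.55-fold, Sdf2l1 by 0.72 log2 and Ddit4, an inhibitor of mTORC1, by 0.86. The list's median was 0.26, with camera adjusted p = 1.15e-06, and adjusted p = 0.232 with an estimated correlation. Of 24 immediate early genes, 3 fell and 0 rose, and adjusted over the list alone 6 were lower. Egr1 changed by -0.70 and Dusp6, a phosphatase of ERK, by -0.76. The list's camera adjusted p was 0.00315, and adjusted p = 0.0850 with an estimated correlation. Of 25 cytokine and NF-kB genes, 1 rose (Ccl2, by 0.76) and 3 fell, namely Ptgs2, Tnfaip6 at -0.805 and the Cxcr4 ligand gene Cxcl12 at -0.79. Another probe set of Tnfaip6 lay at 0.64 and did not pass.

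Each list of muscle identity or cell cycle genes had at most 2 members past the threshold at 48 h. Of all 11286 genes, 362 passed by their brightest probe set, and the shares in these lists were not tested against that. Many muscle genes lay below the minimum signal, with 18 of 35 sarcomere genes and 11 of 20 early differentiation genes on the array measured. In vehicle 4 h the median of mean signals was 604 for 14 satellite cell markers and 7633 for 17 fibroblast markers. Cell identity was not tested. Of 13 satellite cell and myoblast markers, 2 fell, Cxcr4 and the syndecan gene Sdc4, the latter at -0.72. Of 11 early differentiation genes, 1 fell, the cell cycle inhibitor gene Cdkn1c, at -0.95. Of 18 sarcomere genes, 1 fell, the tropomyosin gene Tpm1, at -0.58, while another of its probe sets lay at 0.16. The log2 change of Myog, a regulator of myoblast differentiation, was 0.18 (SE 0.330, adjusted p = 0.848). It was -0.07 for the intermediate filament gene Des (SE 0.190, adjusted p = 0.905) and 0.12 for the proliferation marker Mki67 (SE 0.195, adjusted p = 0.824). Neither 26 DNA replication genes nor 30 mitosis genes had a member past limma's threshold, while 3 and 4 had an unadjusted p under 0.05. The mitosis list's median was 0.23, with camera adjusted p = 0.00315, adjusted p = 0.733 with an estimated correlation, and a median of 0.19 with adjusted p = 0.147 without NARA 48 h replicate 2. Mstn and Myod1 had mean signals of 34.6 ± 12.7 and 83.9 ± 87.2 (SD, n = 13), below the minimum. Of 15 ubiquitin ligase and atrophy genes, 2 rose, Ddit4 and the muscle ubiquitin ligase gene Trim63, the latter 2.68-fold from 2218 ± 495 to 5961 ± 623.

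The comparison at 4 h asked which genes differed early. The greatest separation by p was that of Hdhd3, a gene of the haloacid dehalogenase family, with a signal of 981 ± 78.5 (SD, n = 2) in NARA and 152 ± 14.4 (SD, n = 4) in vehicle, a log2 difference of 2.35 (SE 0.301, adjusted p = 0.0704). The hydrolase gene Cmbl differed by 1.115 (SE 0.158, adjusted p = 0.0733). Il1b, an inflammatory cytokine, differed by -1.39 (SE 0.232, adjusted p = 0.175) and Ptgs2 by -0.83 (adjusted p = 0.286). None of these passed. Other genes of smallest p were Jade1 at 0.62, Glul, the glutamine synthetase gene, at 0.68, Sult1a1 at 0.96, Ndnf at -0.91, Mdc1 at -1.68 and the Wnt coreceptor gene Lrp5 at -1.67.

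With limma, 0 of 20904 probe sets passed at 4 h, and 992 had an unadjusted p under 0.05. The count was 1 with all 16 arrays, 5 with array weights over them, 3 with only the 4 h groups, 2 with a minimum of 1000 and 9 with a trended and robust prior. Without NARA 4 h replicate 3 the count was 19, and without replicate 2 it was 11; the lone NARA sample was then assumed to vary like the other groups. At 4 h, 14.3% of all probe sets had groups that did not overlap, against 13.3% by chance.

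Known steroid targets at 4 h had log2 differences of 0.82 for Fkbp5 (SE 0.313, adjusted p = 0.967), 0.54 for Tsc22d3, 0.54 for Sgk1, 0.33 for Igf1 and 0.33 for Fst, none past the threshold. Nor did Tmprss2 at 1.56 (SE 0.48) and Cited2 at -0.35 pass in limma. The 19 androgen-responsive genes had a median of 0.09, with camera adjusted p = 0.308. Adjusted over that list alone, 2 were higher and 1 lower. The log2 differences of Myog, Des and Mki67 were -0.04, -0.03 and -0.03. The list of 13 glucocorticoid-responsive genes lay higher, with a median of 0.10, camera adjusted p = 0.0106 and adjusted p = 0.104 with an estimated correlation. Of these, 3 were higher and 0 lower when adjusted over the list alone. The 25 cytokine and NF-kB genes lay lower, with a median of -0.21, camera adjusted p = 0.0110 and adjusted p = 0.104 with an estimated correlation. As adjusted over the list alone, 1 was higher and 2 were lower. The 30 mitosis genes lay lower, with a median of -0.18, camera adjusted p = 0.0214 and adjusted p = 0.923 with an estimated correlation. This call was lost without vehicle 4 h replicate 1 (median -0.138, adjusted p = 0.121), without vehicle 4 h replicate 3 (-0.037, adjusted p = 0.922) and without NARA 4 h replicate 3, where the median was -0.006 and camera's direction turned (adjusted p = 0.815). Without NARA 4 h replicate 3, the glucocorticoid and cytokine lists had medians of 0.08 and -0.12, with adjusted p = 0.190 each, and 0 lists passed at 4 h.

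The difference between the 48 h and the 4 h effect was tested directly. The effect of NARA on Igf1 was greater at 48 h by 1.27 log2 units (SE 0.179, adjusted p = 0.0226). It was greater by 2.86 for Ces1d (SE 0.423, adjusted p = 0.0275), by 1.98 for Tent5b and by 1.63 for Srpx (adjusted p = 0.00961). For Ptgs2 the difference was -1.48 (SE 0.220, adjusted p = 0.0275), and for Grem1 it was -1.25 (SE 0.169, adjusted p = 0.0203). The difference was 1.83 for Fst (adjusted p = 0.0681) and 0.99 for Fkbp5 (adjusted p = 0.524), neither past the threshold.

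In limma, 26 probe sets passed for the difference of effects, 12 positive and 14 negative, and 25 of them differed at least 2-fold. They held 17 genes, 10 positive and 7 negative. The count was 1 without vehicle 48 h replicate 3, 5 without NARA 4 h replicate 3, 8 without NARA 4 h replicate 2, 16 without NARA 48 h replicate 4 and 17 without vehicle 48 h replicate 2. It was 0 with all 16 arrays, 61 with vehicle 48 h replicate 1 put back, 46 with an offset of 200, 11 with no signal minimum, 93 with a minimum of 1000 and 126 with a trended and robust prior. With the replicate number as a block it was 0. The 27 genes of the unfolded protein and amino acid responses had a median difference of 0.34, with camera adjusted p = 6.38e-08 and adjusted p = 0.232 with an estimated correlation. Adjusted over the list alone, 6 of them were higher and 0 lower. The mitosis list had a median of 0.39, with camera adjusted p = 2.81e-05 and adjusted p = 0.766 with an estimated correlation. The immediate early list had a median of -0.17, with camera adjusted p = 0.0113 and adjusted p = 0.183 with an estimated correlation, and 0 higher and 2 lower members adjusted over the list alone. Without NARA 4 h replicate 3, the mitosis and immediate early lists had medians of 0.22 and -0.21, with adjusted p = 0.158 each.

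**Figure D3:**
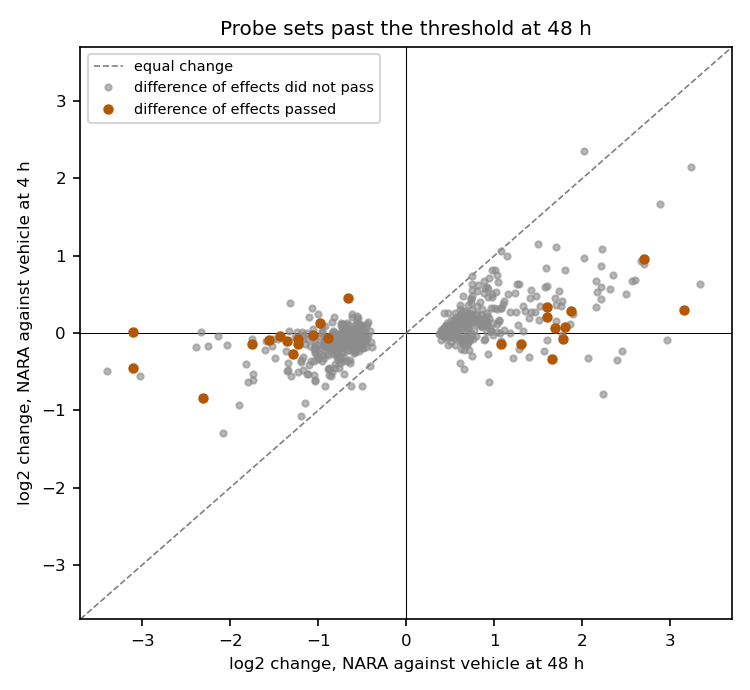
Log2 change with NARA at 48 h (horizontal axis) and at 4 h (vertical axis) for the 586 probe sets that passed at 48 h, with 1 point per probe set, a dashed line of equal change and orange points where the difference of effects passed. The median size of the change was 0.76 at 48 h, and the median 4 h change in the 48 h direction was 0.12.

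Time in culture was compared within vehicle, at 48 h against 4 h. Of 30 mitosis genes, 0 had a positive log2 change and 0 passed singly, with a median of -0.53. Camera gave adjusted p = 9.80e-20 for this list, and adjusted p = 0.434 with an estimated correlation. Ccnb1, the cyclin of mitotic entry, had a signal of 1224 ± 62.9 (SD, n = 3) at 48 h and 2458 ± 560 (SD, n = 4) at 4 h. Mad2l1, a spindle checkpoint gene, had 865 ± 13.7 and 1666 ± 315. Fst had 616 ± 218 and 1261 ± 262. None of these passed singly, with adjusted p = 0.421 for Ccnb1, Mad2l1 and Fst in limma.

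Adjusted over the list alone, 0 mitosis genes were higher and 13 lower, among them Pbk at -1.10 and Ccna2 at -0.99. The 26 DNA replication genes had a median of -0.22, with camera adjusted p = 3.84e-07 and adjusted p = 0.407 with an estimated correlation. Of these, 0 were higher and 5 lower adjusted over the list alone, such as Gins1 at -0.95 and Tk1 at -0.72. The 19 cholesterol synthesis genes had a median of -0.16, with camera adjusted p = 0.0238 and adjusted p = 0.560 with an estimated correlation. This call was lost without vehicle 4 h replicate 3 (median -0.11, adjusted p = 0.200) and without vehicle 48 h replicate 4 (median -0.13, adjusted p = 0.432). Nsdhl lay at -0.52 and Acat2 at -0.40, and adjusted over the list alone 0 were higher and 2 lower. With limma 0 probe sets passed, 1536 had an unadjusted p under 0.05, and 2 passed in the fit with array weights. Without vehicle 48 h replicate 2, 2 passed. The groups did not overlap for 8.90% of probe sets, against 5.71% by chance.

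Within NARA, 48 h was set against 4 h. This comparison holds both a longer time in culture and a longer exposure to NARA, and cannot tell them apart. Igf1 rose by 1.36 log2 units (SE 0.134, adjusted p = 0.00114), from 35030 ± 2405 (SD, n = 2) to 90360 ± 7967 (SD, n = 4). Sult1a1 rose by 2.24 (SE 0.182, adjusted p = 0.000327), and Crispld2, Bmper and Ces1d rose by 3.85, 3.14 and 3.14. Hsd11b2, which inactivates glucocorticoids, rose 3.58-fold from 1111 ± 410 to 4010 ± 630, and Thbd, the thrombomodulin gene, rose 3.71-fold. Grem1 fell by 1.64 (SE 0.127, adjusted p = 0.000327), Cxcr4 fell by 2.04 and the alcohol dehydrogenase gene Adh7 fell by 1.70. Among fixed lists, Tgfb2 rose by 1.22, Il1b by 1.61, Col11a1 by 0.91 and Col6a1 by 0.72, while Lum fell by 0.98.

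In limma, 164 probe sets passed within NARA, 102 higher and 62 lower at 48 h, for 66 higher and 32 lower genes, and 80 changed at least 2-fold. The groups of all 164 did not overlap, as for 21.0% of all probe sets against 13.3% by chance. The count was 69 without NARA 4 h replicate 2, 108 without NARA 4 h replicate 3, 79 without NARA 48 h replicate 3 and 81 without NARA 48 h replicate 4. It was 25 with only the NARA groups in the fit, 19 with all 16 arrays, 107 with array weights, 79 with no signal minimum, 325 with a minimum of 1000 and 372 with a trended and robust prior. With the replicate number as a block it was 51. Fst and Fkbp5 differed by 0.83 and 0.92 log2 and did not pass. All 27 genes of the unfolded protein and amino acid responses had a positive log2 change, with a median of 0.26, camera adjusted p = 7.09e-07 and adjusted p = 0.216 with an estimated correlation. Adjusted over the list alone, 3 were higher and 0 lower. The glucocorticoid-responsive list had a median of 0.18, with camera adjusted p = 0.0305 and adjusted p = 0.216 with an estimated correlation, and 1 higher and 0 lower members adjusted over the list alone. That call was lost without NARA 4 h replicate 2 (median 0.15, adjusted p = 0.154) and without NARA 48 h replicate 4 (median 0.19, adjusted p = 0.0544).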

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

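Tests chosen only after the result was seen were those of the liver list as a separate pattern, of RNA quality and dim signals in vehicle 48 h replicate 1, of a growing response, and the levels of Fabp1, Cyp2c12, Xist, Eif2s3y, Lum, S100a4 and Spry1 in NARA 4 h replicates 1 and 4.

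NARA 4 h replicates 1 and 4, outside the comparisons, showed liver genes far above all other arrays: the median of the liver list was 8.73 and 8.84 log2 units over the vehicle 4 h mean. All 12 members were over 8-fold higher in both arrays, which degradation of the cells' own RNA does not bring about, and a NARA response is argued against by a slope of 0.0149 of replicates 2 and 3 on these shifts. The actin 3'/5' ratio was at least 4.96 in both arrays against 3.38 or less in the other 14, so partly degraded RNA stays open as an addition. RNA of liver in place of the cells' own is a candidate source, in line with the fibroblast list at -2.63, but the prediction behind the 8.73 also required lower satellite cell markers, which lay at medians of 0.38 and 0.54 over members that went both ways, from Cxcr4 (-5.09 and -3.12) to Spry1 (1.92 and 2.35), and so decide nothing. A mix-up of samples or of deposited arrays was not tested apart from this, and no biological explanation other than NARA was tested.

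Alb had signals of 191486 and 288154 in these arrays (431 to 980 in the other 14), Apoa1 135653 and 100454 (33.3 to 245) and Fabp1 206749 and 264143. Lum had 20.3 and 123 (19581 to 46151), and S100a4 287 and 431 (100422 to 139012). Xist had 46120 and 37641 (21.7 to 297) while the Y-linked Eif2s3y had 47.5 and 87.6 (7767 to 13186), and the female-typical liver enzyme gene Cyp2c12 had 161058 and 183854 (14.3 to 235). In both arrays Xist thus lay above, and Eif2s3y, Lum and S100a4 below, the range of the other 14. These values argue against the cells of the other arrays as the main source of this RNA. Of the 12 liver genes, 6 reached a mean signal of 300 in the vehicle 4 h arrays and 1 is also on another list. Of 18 tissue lists, liver alone was over 3 in both arrays, and 5 were over 1 in both: beside liver, the lists for myeloid cells (2.92 and 2.98), epithelium (2.06 and 1.57), lymphoid cells (1.18 and 1.94) and endothelium (1.60 and 1.64). The other 13 lay between -0.22 and 1.26. The extracellular matrix list lay at -2.82 and -2.99, and the mitosis list at -2.58 and -2.35. In both arrays 771 of 22059 probe sets were over 8-fold higher and 528 over 8-fold lower.

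Vehicle 48 h replicate 1, left out by the authors, correlated less with the 13 arrays than they did with each other. Degraded RNA is argued against by its actin 3'/5' ratio of 2.83, within the range of the 13 arrays. The liver list lay at 0.389 against its own group (0.227 or less in the other 13 arrays), short of the log2 difference of 1 set as the mark of such RNA, and it was 1 of 8 of the 18 tissue lists above the range of those arrays, with heart at 1.00, epithelium at 0.60, lung at 0.54 and myeloid cells at 0.44. A small amount of liver RNA therefore cannot be told apart from a rise shared with other lists. Raised signals of dim probe sets are consistent with its position: the median deviation of 10138 dim probe sets was 0.196, against -0.182 to 0.0838 in the other arrays, though neither what raised them nor a biological explanation was tested.

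While 586 probe sets passed at 48 h, 0 did at 4 h in limma, with 992 at an unadjusted p under 0.05. The smaller NARA group at 4 h is argued against as the whole reason, since with 2 of the 4 NARA 48 h arrays at least 238 probe sets still passed, and 308.5 in the median of 6 pairs. A response that grows with time stays open: the median 4 h change of 0.121 in the 48 h direction, against 0.763 at 48 h, belongs to probe sets picked at 48 h and does not test it, while the difference of effects itself passed for 26 probe sets. Of the 35 splits of the 7 arrays at 48 h, the real one was 1 and gave 586 probe sets, and the highest other gave 2. A chance split is argued against, but 1 of 35 is the smallest share this test can reach. The other splits also mix NARA and vehicle arrays within a group, which widens their spread and lowers their counts. For time in vehicle the real split gave 0 and the highest other 2; all 35 splits must reach a count of 0, so this test decides nothing.

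The effect of NARA differed between 48 h and 4 h for 26 probe sets. The positive differences, in log2 units at 48 h minus 4 h, were Ces1d 2.86, Tent5b 1.98, Msra 1.86, Sult1a1 1.74, Lrrn3 1.73, Srpx 1.63, Thbd 1.44, Lmo4 1.38, Igf1 1.27 and Arl15 1.21. The negative ones were Ptgs2 -1.48, Osr2 -1.47, Grem1 -1.25, Olfml2a -1.16, Tk2 -1.11, Lum -1.03 and Dab2 -0.83. Of these 17 genes, 1 passed without each array in turn, and all 17 kept their direction.

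A single array stood far from the other 3 of its group in 3 of 196 groups examined, where chance gives about 9.8. Gbp2 had a log2 signal of 11.92 in NARA 48 h replicate 3 (11.44 to 11.5 in the others). Serpinb11 had 9.307 in vehicle 4 h replicate 1 (10.1 to 10.2). The Gapdh 3'/5' ratio was 1.301 in NARA 48 h replicate 2 (1.064 to 1.096 in the others of its group). It was higher, at 1.363, in vehicle 48 h replicate 2.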

How the results depend on the processing

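The fit of 14 arrays was chosen after the data were seen; all other alternatives were planned. Signals near the background limit what the dim probe sets can show, and the cause of a changed value was not tested unless stated. For the named genes called at 48 h, counted once per gene and alternative, 599 values kept direction and call, 132 lost the call and 3 turned. With 1 array left out, 661 kept the call and 115 lost it.

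With all 16 arrays, which adds NARA 4 h replicates 1 and 4 and vehicle 48 h replicate 1, the counts of probe sets were 36 (NARA at 48 h), 1 (NARA at 4 h), 0 (difference of effects) and 19 (time in NARA), and those of lists 13 (4 h), 13 (difference) and 12 (time in NARA). With vehicle 48 h replicate 1 alone put back, 774 probe sets passed at 48 h and 146 for time in NARA. Array weights gave 5 at 4 h, 107 for time in NARA and 2 for time in vehicle. Those weights were 0.0593 and 0.0623 for NARA 4 h replicates 1 and 4 and at least 0.885 for the others. With all 16 arrays directions turned for the difference of effects of Dab2 (0.43), Grem1 (1.95), Lum (3.29), Olfml2a (0.135), Osr2 (0.715), Ptgs2 (0.063) and Sult1a1 (-0.064). They turned for time in NARA of Grem1 (1.56), Osr2 (0.74), Ptgs2 (0.24) and the glucocorticoid list (-0.97), and at 4 h for Fst (-0.46), Myog (0.30) and the cytokine list (0.22). All these comparisons use the NARA 4 h group, to which replicates 1 and 4 with their high liver genes were added. There Lum was 602-fold and 244-fold below the vehicle 4 h mean, and Sult1a1 27.3-fold and 21.8-fold above it. Both arrays also enter the spread shared by all groups. This setting therefore does not show how the other 14 arrays depend on processing.

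Only the groups compared in the fit, and so fewer arrays for the spread, gave 218 (48 h), 3 (4 h) and 25 (time in NARA). No signal minimum gave 355 (48 h), 11 (difference) and 79 (time in NARA), and 1 list for time in NARA. A minimum of 1000 gave 1069 (48 h), 2 (4 h), 93 (difference) and 325 (time in NARA), and 1 list for time in NARA. The trended and robust prior gave 1098, 9, 126 and 372 in the same order. An offset of 200 gave 46 for the difference, and 14 arrays gave 61. Quantile scaling gave 4 lists for time in NARA. An estimated correlation left 0 lists in each of the 5 comparisons; fry gave 0 at 4 h, 8 at 48 h, 2 for the difference, 0 for time in vehicle and 4 for time in NARA. The 8 at 48 h were, higher, the androgen, glucocorticoid and unfolded protein lists and, lower, the polyamine, Wnt and Notch, immediate early, cytokine and steroid receptor lists, the last with a median of 0.03. Of 27 other probe sets of 21 genes called at 48 h, 16 kept direction and passed, 8 kept direction without passing, and 3 turned: Dkk3 (0.59), Tnfaip6 (0.64) and Tpm1 (0.16).

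With the replicate number as a block, the counts were 312 (48 h), 0 (difference) and 51 (time in NARA), with 1 list for time in NARA, and Des at 48 h turned to 0.017. No pairing of samples by number was seen in the deviations left after each group's mean was subtracted from every probe set. These deviations of same-numbered arrays of different groups correlated at a median of 0.0109 over 16 pairs, 0 of them above 0.1. By the same measure, 2 of 13 arrays correlated best with their own number among the arrays of other groups.

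Leaving out each array gave 310 to 528 probe sets at 48 h, 0 to 19 at 4 h, 1 to 36 for the difference, 0 to 2 for time in vehicle and 69 to 157 for time in NARA. The lists were 3 to 5, 0 to 5, 1 to 4, 2 to 4 and 1 to 6 in that order. Ranges that crossed 0 were those of Des at 4 h (-0.223 to 0.16) and 48 h (-0.146 to 0.071), Mki67 at 4 h (-0.273 to 0.216) and Myog at 4 h (-0.334 to 0.262) and 48 h (-0.003 to 0.396). The mitosis list at 4 h had medians of -0.366 to -0.006, with the camera direction turned in 1 setting.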

Other observations

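The test of an early start was chosen only after the result was seen; that of the mitosis list was planned.

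Several groups not described so far had single members past the threshold with NARA at 48 h, or none. Of 14 heat shock genes, 1 rose, the cochaperone gene Dnaja1, by 0.47 log2. Of 23 interferon-stimulated genes, 1 fell, the guanylate-binding protein gene Gbp2, at -0.59. Of 14 cell cycle inhibitors and p53 targets, 1 fell, Cdkn1c, and adjusted over the list alone 2 were higher and 3 lower. Of 25 glycolysis and hypoxia genes, 0 passed in limma and 5 had an unadjusted p under 0.05, with Pfkp, a phosphofructokinase gene, at -0.52 (adjusted p = 0.0513). Markers of other cell types had 0 members past the threshold in limma. An unadjusted p under 0.05 was found for 1 of 17 genes of smooth muscle and pericytes, 2 of 15 of adipocytes, 1 of 6 of bone and cartilage, 0 of 8 of endothelium, 2 of 9 of macrophages and leukocytes and 1 of 9 of Schwann cells. In the same way 0 passed, with an unadjusted p under 0.05 for 6 of 19 cholesterol synthesis genes, 1 of 20 of oxidative phosphorylation, 0 of 15 ribosomal proteins, 3 of 22 of ribosome biogenesis and 1 of 15 NRF2 targets.

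Probe sets changed at 48 h were examined at 4 h as a hypothesis that the same response may have begun early. Of the 586, 455 (77.6%) had the same direction at 4 h, against 52.8% of all probe sets. With an estimated correlation, camera gave p = 7.52e-05 for the 285 higher and p = 0.00482 for the 301 lower probe sets in those directions. The vehicle arrays and NARA arrays of the 4 h and 48 h comparisons are different, so the comparisons share no control, though they share the estimate of the spread.

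The lower mitosis list at 48 h in vehicle did not rest on 1 array: the highest camera adjusted p without 1 array was 1.50e-13 at the preset correlation, while adjusted p = 0.434 with an estimated correlation. Medians of the list against the vehicle 4 h mean were -0.35 to 0.44 in the vehicle 4 h arrays, -0.62 to -0.46 in vehicle 48 h and -0.46 to -0.15 in NARA 48 h. They were -0.01 and -0.37 in NARA 4 h replicates 2 and 3.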
